A study of Homo sapiens with 4 samples.

How the data were processed

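Total RNA of the cell lines MyLa and HH, cultured for 40 hours in 0.1% serum without or with 5 ng/ml of IL-32γ, was labelled with biotin after a single amplification, per the labels, and hybridised to 4 arrays, 1 per line and condition. The values are log2 expression values per probe set, deposited after GCRMA, which corrects background by probe sequence, normalises over arrays and summarises probes, per the submitters' processing notes. The version of GCRMA, and whether the 4 arrays were normalised together, are not given in the sources used here. That the scale is log2 was read from the values, which ran from 2.13 to 16.0. On each array 50.5% to 51.1% of the 54675 probe sets lay below 3, so a level of 5 was taken as the floor of measurement, above which lay 42.9% to 43.3% of them.

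Gene symbols came from the array's annotation table, updated through the Entrez identifier with a RefSeq gene table of assembly GRCh38.p14, used for names alone. Of the probe sets, 41097 had 1 symbol, 1801 had several and were not named, and 11777 were not listed. The update matched 41043 of those with 1 symbol. They covered 19775 genes, 10523 of them with several probe sets, and the probe set with the highest mean over the 4 arrays stood for the gene. XIST and Y-linked genes were not named, but they stayed in the counts and fits.

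Within a line the difference was the IL-32γ value minus the control value, after setting values below 5 to 5, for genes at 5 or more on at least 1 of the 2 arrays. With 1 array per condition there is no test of it, and genes at 1.5-fold or more were counted. A gene measured on 1 side only has a bound, given as at least that fold. Between lines such a bound compares the bright line's mean with the mean of the other line's values raised to 5.

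For IL-32γ across lines, limma 3.58.1 in R 4.3.3 was fitted to genes at 5 or more on at least 2 arrays, with the line as a block because each treated array has its control in the same line. This left 1 residual degree of freedom. MyLa was compared with HH in limma without a block, with the 2 arrays of a line as its replicates and 2 residual degrees of freedom. Their spread therefore holds the IL-32γ response as well as noise, and nothing in the labels makes them separate cultures of 1 condition. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and a 2-fold minimum was set between lines.

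The designs, the alternatives, the rule for named genes and 50 gene lists, 41 of gene functions and 9 of cell type markers, were fixed before the data were examined. The lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, for lists with 5 or more tested members. Within a line a list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The rule named, per line, the 12 highest and 12 lowest differences among genes measured on both arrays and the 5 brightest genes measured on 1 array only in each direction. It also named the 12 genes higher and 12 lower in both lines, the 15 largest differences between lines per direction with the 10 brightest genes of 1 line only, and up to 4 members of each list. Members of the Th2, Th9 and IL-32 lists, and the 8 genes whose responses differed most per direction, completed it. A few further list members are given beside these and were chosen after their values were seen, among them PFKFB4 in MyLa, HK1, SLC30A1 and MTF1.

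The fits were tested on simulated data with 200 of 11010 genes changed, 50 at each size. With gene variances drawn from the fitted prior, the IL-32γ fit recovered 0, 40, 48 and 45 of 50 genes changed by 2-, 4-, 8- and 16-fold, with 4 false calls among 137. The line fit then recovered 5, 38, 46 and 44, with 6 false among 139. With the moderated variances of the real fit, the IL-32γ fit recovered 48, 50, 50 and 50 but made 79 false calls among 277 (28.5%), far above the nominal 5%, so its error rate depends on how gene variances spread. The line fit recovered 16, 47, 50 and 50 with 6 false among 169. The percentile of a planted list came out above all random lists, and 0 of 20 unshifted lists fell outside the central 95%. These lists were of randomly drawn genes, so genes that move together were not tried.

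Alternatives were floors of 4 and 6 or none, quantile, loess or median-centred values, the mean of a gene's probe sets, leaving out probe sets that can match several transcripts, other fold thresholds, an intensity trend, other blocks, and leaving out each array. The filter on measured genes was moved with the floor, and dropped where there was no floor. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9. Scanner files were not used here.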

Results

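Gene expression was measured on 4 oligonucleotide arrays of 54675 probe sets each, hybridised with biotin-labelled total RNA of 2 human cutaneous T cell lymphoma lines. MyLa is a line of mycosis fungoides, the commonest such lymphoma, and HH is a cutaneous T cell lymphoma line. Each line was cultured for 40 hours in 0.1% serum, without (control) or with 5 ng/ml of IL-32γ, an isoform of interleukin-32, which is a cytokine made by T cells, NK cells and epithelial cells. The title of the series concerns IL-32 in mycosis fungoides and its relation to Th2 and Th9 cells, so the question taken up here is what IL-32γ does to the transcripts of the lines. There was 1 array per condition. A difference within a line therefore has no replicate check, is given as a value with no test, and the number of arrays limits its precision.

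The arrays held similar numbers of measured probe sets, from 23433 on the HH control array to 23686 on the MyLa control array, with log2 values of 5 or more taken as measured. Over all probe sets the 2 arrays of MyLa correlated at r = 0.994 and those of HH at r = 0.997, while the control arrays of the 2 lines correlated at r = 0.908. These correlations are across probe sets, which are not independent. The spike-in hybridisation controls differed by a mean of -0.08 (log2, MyLa IL-32γ minus control) and -0.01 (HH). The control probe sets near the 5' end of transcripts did not stay level. The 5' ACTB probe set read 10.12 on the MyLa control array, 11.81 on the MyLa IL-32γ array, 12.69 on the HH control array and 13.58 on the HH IL-32γ array, while its 3' partner lay between 15.07 and 15.27. The 5' GAPDH probe set was higher by 0.68 in MyLa and by 0.15 in HH with IL-32γ, and the 18S rRNA probe set by 0.63 and 1.59.

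**Figure D1:**
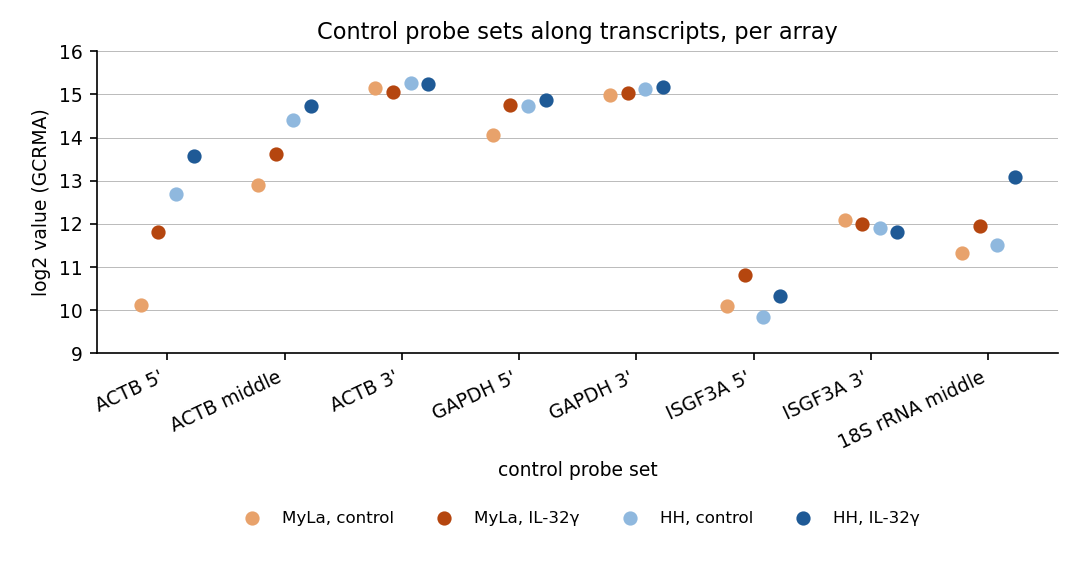
Log2 values of control probe sets (x axis, named by transcript and position) on each of the 4 arrays (points, coloured by line and treatment; 1 array per condition). In both lines the 5' ACTB value is higher on the IL-32γ array, 11.81 against 10.12 in MyLa and 13.58 against 12.69 in HH, and the 3' values are nearly level.

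In MyLa, IL-32γ-treated cells had higher values of metallothionein genes, which bind zinc and copper, and of several cytokine genes, among them TGFB1 (5.51-fold), LTB, encoding lymphotoxin beta (log2 difference 1.57), and the chemokine CCL5 (log2 difference 1.55). TGFB1, with no other measured probe set, read 5.94 on the MyLa control array and 8.40 with IL-32γ, against 8.78 and 8.49 in HH. Its difference thus rests on a low value on 1 array. The interferon-stimulated gene ISG15 was higher by 1.23, while IFIT1 of the same list was lower (-0.76) and the list of 16 genes had a median of -0.066 (percentile 51.4). Higher too was BATF, a transcription factor of Th2, Th9 and Th17 cells (1.19). Lower values were seen for the pore-forming protein gene GSDME (-1.80), the T cell transcription factor gene NFATC1 (-2.02) and the growth factor gene CSF1 (-1.06). With IL-32γ, GSDME read 5.29 and NFATC1 5.07, close to the floor of 5, and neither had another measured probe set. Of 10497 genes measured on at least 1 of the 2 arrays, 816 (7.77%) were higher by 1.5-fold or more and 803 (7.65%) lower.

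The highest IL-32γ values relative to control among genes measured on both MyLa arrays were those of RAB11B, a GTPase of recycling endosomes (10.1-fold), PTP4A3, a phosphatase (9.23-fold), RARA, the retinoic acid receptor alpha (9.02-fold), LOC100505915 (7.66-fold), MGRN1, a ubiquitin ligase (7.60-fold), MORC2-AS1 (5.86-fold), ALKBH6 (5.80-fold), TGFB1, UQCRC1, a subunit of respiratory complex III (5.30-fold), PPDPF (5.30-fold), BCORL1 (5.28-fold) and ZNF414 (4.79-fold). Other measured probe sets of these genes gave smaller differences for RAB11B (0.70), PTP4A3 (1.12) and RARA (0.18 and 0.19), and similar ones for PPDPF (2.41 and 2.69). The lowest were BRINP3 (-2.06), NFATC1, ACOT11 (-1.90), the sodium channel gene SCN11A (-1.89), TMEM132D (-1.85), EML6 (-1.82), PLCD3 (-1.82), GSDME, which forms pores in pyroptosis (-1.80), the cell cycle repressor E2F4 (-1.75), RHBDF1 (-1.75), PPFIBP2 (-1.66) and CYFIP1 (-1.59). For E2F4 the other probe set was at -0.72, and for SCN11A the other 2 lay at -1.42 and -0.88. EML6 (5.03), RHBDF1 (5.14), ACOT11 (5.21), TMEM132D (5.48) and BRINP3 (5.56) also read close to the floor of 5 with IL-32γ. Among genes below 5 on the control array, AP5B1 was higher by at least 6.97-fold, STARD10 by at least 5.70-fold and ESCO2, a cohesin acetyltransferase, by at least 4.57-fold, and ANKRD9 and ANKRD23 by at least 4.42-fold and 3.96-fold. The other measured probe set of ESCO2 stood at 0.15. MROH8 (-1.76), ANKRD29 (-1.67), AGPAT4-IT1 (-1.59), LAMA5 (-1.58) and LINC01465 (-1.53) went below 5 with IL-32γ, so these differences are bounds.

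Of 41 gene lists with 5 or more measured members in MyLa, the metallothionein list stood highest: 6 of its 8 measured members were higher by 1.5-fold or more, none lower, and its median of 0.84 lay above all 10000 random lists matched on expression. MT2A was higher by 1.13, MT1G by 0.97, MT1H by 0.90, MT1X by 0.79 and MT1E by 0.70, and MT1F by at least 1.00 since it was below 5 without IL-32γ. The other 2 members, the metal-responsive transcription factor MTF1 and the zinc exporter SLC30A1, differed by 0.11 and 0.03. The probe sets of these metallothioneins carry probes shared with related genes, so single members are uncertain. Members that read partly the same signal are not separate evidence. The percentile, set against lists of randomly drawn genes, can therefore overstate the list. The cytokine list had 4 of 16 members higher (TGFB1, LTB and CD70 at 1.22 among them) and 1 lower (CSF1), with a median of 0.24 (percentile 99.8). Pro-apoptotic genes had 3 of 15 higher, BAD (1.27), CASP8 (0.75) and the TRAIL receptor TNFRSF10A (0.73), and 1 lower, CASP9 (-0.81), with a median of 0.18 (percentile 99.4). Anti-apoptotic genes also lay high, with 2 of 12 higher, BCL2L1 (0.73) and the kinase PIM1 (0.82), none lower, and a median of 0.13 (percentile 98.1). These last 2 belong to the JAK-STAT feedback list too, where JAK3 was also higher (0.60) and JAK2 lower (-0.96), with a median of 0.09 (percentile 98.0). As means of their probe sets JAK3 stood at -0.21 and JAK2 at 0.12. The other 2 measured probe sets of BCL2L1 were higher by far more than 0.73, by 2.92 and 3.51, so its size is uncertain. In the regulatory T cell list only TGFB1 of 11 members passed 1.5-fold, IL2RA stood at 0.56 with its other probe set at -0.01, and the median was 0.21 (percentile 98.8). Immediate early genes of MAP kinase signalling had a median of 0.12 (percentile 98.1) with 1 of 20 members past 1.5-fold, SPRY1 (0.62).

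Lists at the low end in MyLa were hypoxia genes (median -0.23, percentile 0.17), with NDRG1 the 1 of 18 members past 1.5-fold (-0.90) and PFKFB4 at -0.58; proteasome subunits (median -0.14, percentile 0.46), in which PSMB5 went the other way (0.69); glycolysis (median -0.15, percentile 1.57), in which PFKL was higher (1.77) and HK1 stood at -0.41; and 5 fibroblast genes (median -0.48, percentile 0.78), with TAGLN (-0.85) and POSTN (at least -1.17) past 1.5-fold. G2/M genes had 3 of 27 higher and 3 lower, UBE2C at 0.92 and CDC25C at -0.87 among them (median -0.22, percentile 4.02). NF-κB targets had 2 of 23 higher, LTB and TNFAIP2 (0.84), and 1 lower, the adhesion molecule ICAM1 (-0.70), with a median of 0.02 (percentile 89.9). As the mean of its probe sets ICAM1 stood at 0.072. In all, 11 of 41 lists lay outside the central 95% of their random lists, where independent lists of unrelated genes would give 2.05. Members of a list can move together and lists share members, so 2.05 is not what chance alone would give here. On the same 2 arrays the 5' ACTB probe set was higher by 1.69 and the 5' GAPDH probe set by 0.68 with IL-32γ. Among 5034 genes with 2 measured probe sets, the response of the probe set brightest in MyLa correlated with that of the second at r = 0.30 across genes, and of 529 genes in which it differed by 1.5-fold or more, 180 had a second probe set past 1.5-fold in the same direction.

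IL-32γ and Th2 and Th9 genes were looked at in both lines. IL32 itself was at 13.45 on the MyLa control array and 13.76 with IL-32γ, and at 13.70 and 13.78 in HH. The integrin subunit ITGAV differed by -0.30 in MyLa and -0.08 in HH. Focal adhesion kinase, PTK2, differed by 0.02 in MyLa and by 0.99 in HH, where it was at 5.61 without IL-32γ. The other 2 measured probe sets of PTK2 in MyLa stood at -1.69 and 0.48. Of the Th2 list, 2 of 7 measured members were higher by 1.5-fold or more in MyLa, IL13 (0.76) and BATF, with IL5 at 0.55, STAT6 at 0.19, MAF at -0.06, GATA3 at -0.22 and IL4R at -0.42 (median 0.19, percentile 96.5). In HH, IL13, IL5 and MAF were below 5, IL4R was lower (-0.78), and GATA3 (-0.24), STAT6 (-0.22) and BATF (-0.02) stayed within 1.5-fold. IL4, IL10, CCR8, PTGDR2, IL1RL1, IL17RB and CCR4 were below 5 on every array. The Th9 list held 12 genes, of which 11 had a probe set here and 9 were measured in MyLa. The cytokine gene IL9 was not among these 9. Of the Th9 list, 2 of 9 members were higher in MyLa, TGFB1 and BATF, with the IL-9 receptor IL9R at 0.52, IRF4 at 0.19, STAT5B at 0.14, ETV5 at 0.10, STAT5A at 0.03, SMAD3 at 0.02 and IRF1 at -0.01 (median 0.14, percentile 95.1). Other MyLa probe sets of these genes went the opposite way for IRF1 (0.62), SMAD3 (-0.48), MAF (up to 1.39) and STAT5B (down to -0.84). In HH none of the 9 reached 1.5-fold, with SMAD3 highest at 0.23 and TGFB1 lowest at -0.29 (median -0.068, percentile 67.8). Neither list gave an adjusted p under 0.05 across the lines (the Th9 list, median 0.12, camera adjusted p = 0.518).

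In HH, fewer genes stood out with IL-32γ. Of 10307 genes, 118 (1.14%) were higher by 1.5-fold or more and 460 (4.46%) lower. Higher values were found for PHKG1, a phosphorylase kinase subunit (3.40-fold), the calmodulin-dependent kinase CAMK1 (3.30-fold), BMS1P2 (3.04-fold), the transcription factor gene LHX4 (2.65-fold), LOC101928697 (2.63-fold), SYNC (2.63-fold), the vesicular monoamine transporter SLC18A2 (2.60-fold), LOC114224 (2.42-fold), SCARNA17 (2.39-fold), PODXL (2.28-fold), MPV17L (2.25-fold) and hepatocyte growth factor, HGF (2.23-fold). LOC100505915, below 5 without IL-32γ, was higher by at least 4.80-fold, and LDLRAD4-AS1, LOC102723704, TMCC1-DT and SND1-IT1 by at least 2.19-fold, 2.07-fold, 2.07-fold and 2.03-fold. The lowest were PHF21B (-1.68), the adaptor DOK3 (-1.64), LOC389906 (-1.60), ST3GAL6 (-1.56), ANKRD11 (-1.44), PTPN13 (-1.43), CAPN14 (-1.34), TNFSF8, the ligand of CD30 (-1.34), VPS9D1 (-1.33), LOC100128988 (-1.32), CYP27B1, which makes active vitamin D (-1.31), and RRAGB (-1.30). The other measured probe set of ANKRD11 was at -0.29, and that of MPV17L at 0.22. Of the 12 higher genes only MPV17L had another. On the HH control array PHKG1 (5.09), SLC18A2 (5.11), SCARNA17 (5.22) and MPV17L (5.42) read close to the floor of 5. LHX4 (5.69), HGF (5.75), CAMK1 (5.85), LOC114224 (5.85) and BMS1P2 (5.91) were little above it. With IL-32γ, PTPN13 (5.14), ST3GAL6 (5.30), PHF21B (5.31), TNFSF8 (5.32), LOC389906 (5.48), ANKRD11 (5.49), DOK3 (5.56) and RRAGB (5.67) were close to it too. DNAI4 (-1.96), KLF3 (-1.91), SLC29A2 (-1.56), THTPA (-1.43) and B4GALNT1 (-1.29) went below 5 with IL-32γ and are bounds.

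Of 38 gene lists in HH, 5 lay outside the central 95% of their random lists, where independent lists of unrelated genes would give 1.90, with the same limit as in MyLa. The metallothionein median was 0.08 (percentile 98.3) with none of 8 members past 1.5-fold and MT1X highest at 0.32. Of cytokine receptor genes, 3 of 22 were lower, IL12RB2, the IL-10 receptor IL10RA (-0.94) and IL4R (median -0.084, percentile 41.1). Pro-apoptotic genes had 2 of 15 lower, BMF (-1.03) and BIK (-0.63; median -0.095, percentile 52.0), and hypoxia genes 2 of 17 lower, PFKFB3 (-0.81) and PFKFB4 (-0.64; median -0.023, percentile 59.6). Type I interferon genes had 1 of 17 lower, IFIT3 (-0.82; median -0.062, percentile 79.6). These 4 lists lay within the central 95% of their random lists. The MHC class II and interferon gamma list had a median of 0.05 (percentile 98.4), with HLA-DRA at 0.28 and HLA-DPB1 at 0.21, its other probe set at -0.068. The Th17 list had a median of 0.12 (percentile 99.1) with STAT3 at 0.45, fatty acid synthesis one of -0.31 (percentile 0.90) with SREBF1 lower (-0.63), and oxidative phosphorylation one of -0.04 (percentile 1.88) with CYC1 at -0.27. On these 2 arrays the 5' ACTB probe set was higher by 0.89 and the 18S rRNA probe set by 1.59 with IL-32γ. Of 119 genes whose probe set brightest in HH differed by 1.5-fold or more and had a second measured one, 31 (26.1%) had the second past 1.5-fold the same way, and 84 (70.6%) had a second probe set of the same sign, 14 of the 35 higher (40.0%) and 70 of the 84 lower (83.3%).

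**Figure D2:**
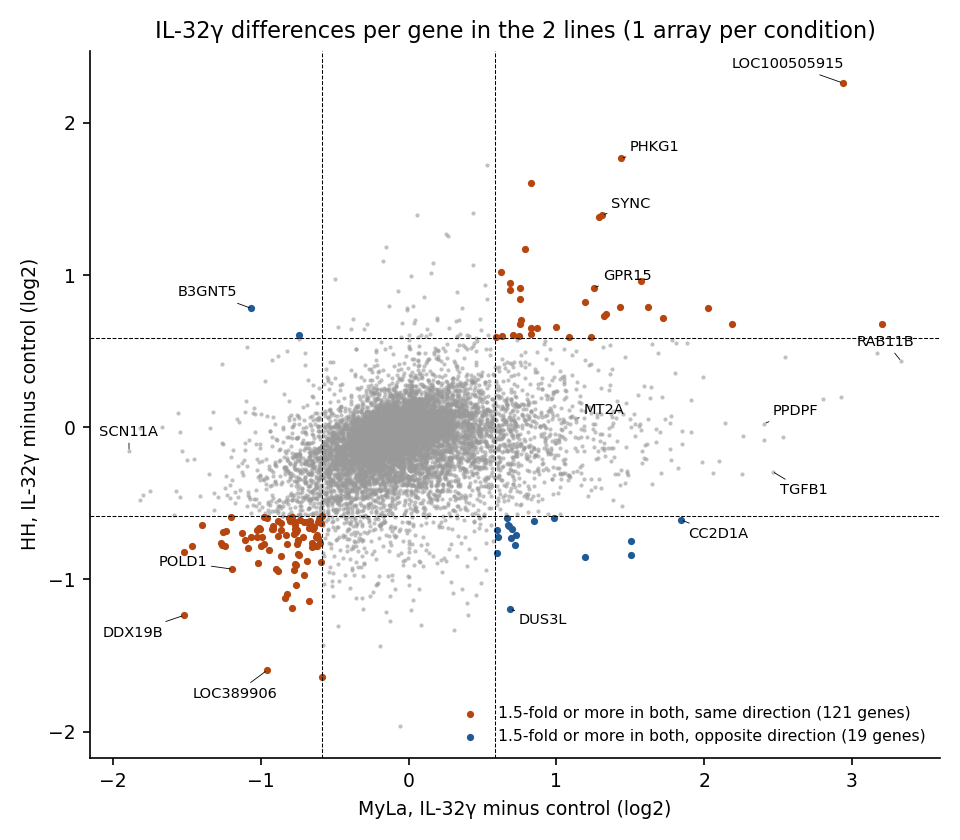
Log2 difference between the IL-32γ and the control array in MyLa (x axis) and in HH (y axis), 1 point per gene measured in both lines, values below 5 set to 5, dashed lines at 1.5-fold. The 121 genes past 1.5-fold the same way in both lines are orange and the 19 that go opposite ways are blue. LOC100505915 lies at 2.94 in MyLa and 2.26 in HH, where it is a bound.

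Some genes passed 1.5-fold the same way in both lines. Of 9545 genes measured in both, 34 were higher in both by 1.5-fold or more, where independent lists would share 6.55, and 87 were lower in both, against 23.2. Another 17 were higher in MyLa and lower in HH, against 27.4, and 2 went the other way, against 5.53. Among 4604 genes with 2 or more measured probe sets in each line, the probe set standing for the gene placed 12 higher and 20 lower in both. When every measured probe set had to pass 1.5-fold, 0 were higher in both and 5 lower. Across the 9324 genes measured on all 4 arrays the responses correlated at r = 0.31 (Spearman 0.34), a description across genes that are not independent. Ranked by the smaller of their 2 differences, the genes highest in both were LOC100505915, PHKG1 (a mean log2 difference of 1.60), SYNC (1.35), SLC18A2 (1.34), ADD3-AS1 (1.27), the gut and skin homing receptor GPR15 (1.08), BMS1P2 (1.21), the linker histone gene H1-3 (1.01), RFFL (1.21), GNRHR2 (1.11), MPV17L (0.98) and TAF8, a TFIID subunit (1.40). PHKG1 was below 5 on the MyLa control array, and LOC100505915 and ADD3-AS1 on the HH control array, so their differences there are bounds. The other probe set of RFFL went the opposite way (-0.55), that of TAF8 the same way (1.26), and that of MPV17L stood at only 0.11. By the same ranking the lowest in both were the RNA helicase DDX19B (-1.38), LOC389906 (-1.28), the DNA polymerase delta catalytic subunit POLD1 (-1.06), BYSL, a ribosome assembly factor (-0.92), sulfite oxidase, SUOX (-0.96), BBOF1 (-0.91), PPP1R13B, a p53 partner (-0.85), PIWIL4 (-0.98), CCDC150 (-1.17), the autophagy gene ATG2A (-0.96), MTCL1 (-0.88) and FBXO36 (-0.94). In both lines the 5' ACTB probe set was higher on the IL-32γ array, by 1.69 and 0.89.

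With the lines as replicates (n = 2 lines), no gene of 11010 passed an adjusted p of 0.05 in limma with the line as a block, which has 1 residual degree of freedom. At an unadjusted p under 0.05 there were 178 genes higher and 867 lower, together 9.49% of those tested. Some genes pass such a threshold by chance. In this fit the square root of the median moderated variance of genes was 0.125. The median log2 difference was negative in both lines, -0.068 in MyLa and -0.068 in HH. This shared offset was not removed before the fit and can add to the lower side. How much of the excess of lower genes it accounts for was not tested. Of the lists, only the metallothioneins passed camera with its preset correlation of 0.01 (8 genes, median 0.50, adjusted p = 0.00287). That p rests on genes, not arrays, as replicates. Since these genes share probes, their correlation can be well above the preset one, which would make the p too small. The call was lost without the line as a block (adjusted p = 0.686), where the line difference enters the spread. It was also lost with an estimated correlation (adjusted p = 0.932), which with 1 residual degree of freedom can call hardly any list and does not decide the question. MT1X differed by 0.56 ± 0.17 (SE) across lines (adjusted p = 0.523) and MT2A by 0.59 ± 0.32 (adjusted p = 0.579).

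The difference between the lines in their responses cannot be tested with the 4 arrays. Among genes measured on all 4 arrays it was greatest on the MyLa side for RAB11B (2.90), TGFB1 (2.75), MGRN1 (2.73), RARA (2.69), ALKBH6 (2.60), DMAP1 (2.56), PTP4A3 (2.53) and UQCRC1 (2.49). Each of these 8 genes was lower on the MyLa control array than on any other array. On the other side, again among genes measured on all 4 arrays, were EML6 (-1.81), SCN11A (-1.73), FANCG, a Fanconi anaemia gene (-1.68), PABIR3 (-1.65), SLFNL1 (-1.62), PGM2L1 (-1.52), PHB1P19 (-1.47) and the aquaglyceroporin AQP3 (-1.38). The other measured probe set of PGM2L1 in MyLa went the opposite way (0.41).

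The 2 lines differed from each other far more than either did with IL-32γ. MyLa expressed CD8A at 11.06 and the costimulatory receptor ICOS at 13.69 (both log2, mean of 2 arrays) with neither measured in HH, while HH expressed CD4, CD5 and CD6, each below 5 in MyLa. MyLa was higher in the Th2 cytokine genes IL13 and IL5, the IL-2 receptor gene IL2RA and the p53 targets CDKN1A and GADD45A. HH was higher in the MHC class II genes HLA-DRA, HLA-DQA1 and HLA-DQB1, in 20 of 27 G2/M genes and in the metallothionein genes MT1E and MT1F. With the 2 arrays of a line taken as its replicates, 2166 of 11010 genes were higher in MyLa and 1925 higher in HH (limma, adjusted p under 0.05 and at least 2-fold). The 5' ACTB probe set was lower on both MyLa arrays (10.12 and 11.81) than on both HH arrays (12.69 and 13.58).

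Among genes measured on all 4 arrays the differences in favour of MyLa were led by LINC02693 (148-fold), SNX7 (145-fold), the axon guidance receptor ROBO1 (125-fold), DUXAP10 (124-fold), DNAJA4 (115-fold), the glycolytic regulator PFKFB3 (112-fold), DENND2B (98.7-fold), DLGAP1-AS1 (91.8-fold), ITM2A (89.8-fold), ATXN1 (82.5-fold), PTK2 (82.0-fold), NR4A3 (81.0-fold), cathepsin B, CTSB (78.9-fold), GADD45A (78.3-fold) and LHFPL6 (77.8-fold). Of the 778 genes higher in MyLa that were below 5 on both HH arrays, the brightest were the platelet chemokine PPBP (at least 876-fold), DNAJC12 (at least 707-fold), SYT4 (661-fold), FERMT2 (569-fold), PARP12 (513-fold), monoamine oxidase A, MAOA (497-fold), RAI14 (489-fold), LOC102723692 (475-fold), CTNNA1 (452-fold) and ICOS (413-fold), all as lower bounds. In favour of HH were the TNF receptor gene TNFRSF1B (101-fold), JAML (log2 difference -6.58, MyLa minus HH), NDRG1 (95.9-fold), SEPTIN3 (90.2-fold), TIAM1 (82.5-fold), RCN1 (79.6-fold), LDLRAD3 (77.9-fold), MAN1A1 (77.1-fold), the transcription factor genes MEF2C (71.7-fold) and FOXP2 (53.6-fold), DPF3 (66.4-fold), PLXNC1 (52.1-fold), COTL1 (49.0-fold), LINC03024 (47.5-fold) and RGS9 (39.7-fold). For PLXNC1 the other 2 probe sets differed by only -0.36 and -0.11 (log2). The brightest of the 652 genes below 5 on both MyLa arrays were TPRG1 (at least 718-fold), the glutathione transferase GSTP1 (657-fold), HLA-DRA (576-fold), HAND1 (558-fold), CDCA7L (538-fold), PRDX2 (505-fold), SPTBN1 (483-fold), GLUL (472-fold), HLA-DQA1 (453-fold) and the adhesion molecule CADM1 (436-fold), again as lower bounds. PRDX2 had another probe set measured in both lines, which differed by only -0.58.

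**Figure D3:**
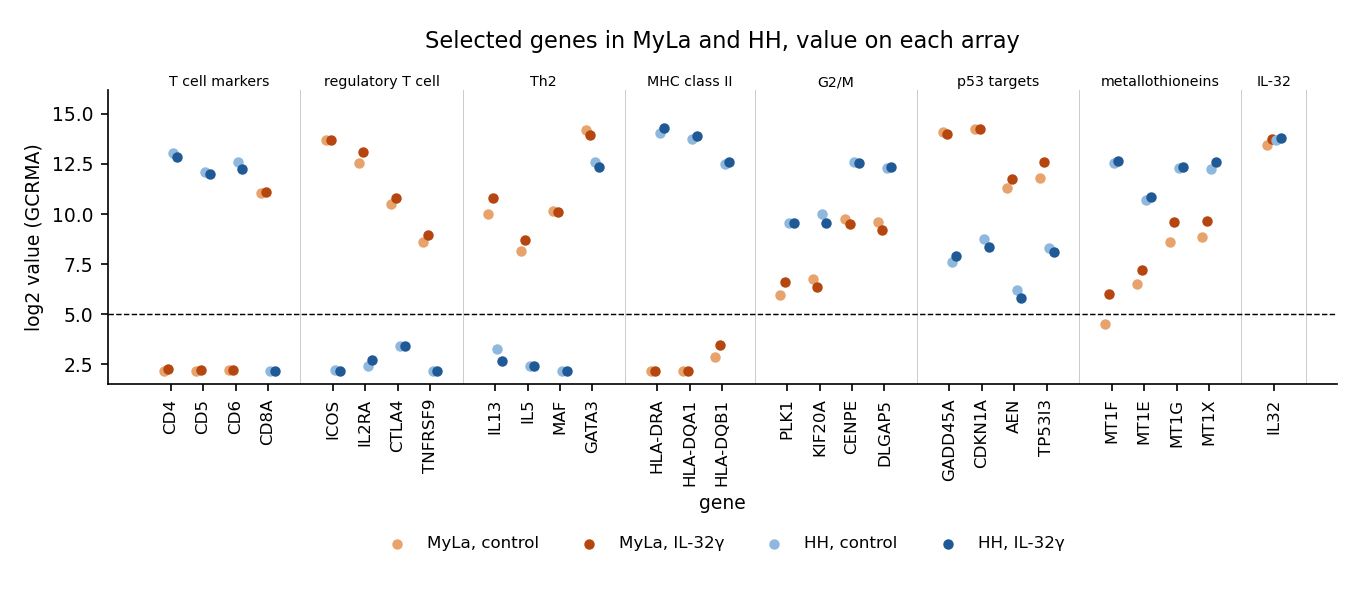
Log2 values (y axis) of selected genes (x axis, grouped by list) on each of the 4 arrays, with the dashed line at 5, below which a gene is taken as not measured. CD4, CD5, CD6, HLA-DRA, HLA-DQA1 and HLA-DQB1 are measured in HH alone, CD8A and ICOS in MyLa alone, and IL32 lies between 13.45 and 13.78 on the 4 arrays.

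T cell surface and signalling genes split between the lines. Of 13 tested T cell markers, 8 were higher in HH and 2 in MyLa (10 adjusted over the list alone), with CD4 at least 246-fold, CD6 at least 173-fold and CD5 at least 131-fold higher in HH and CD8A at least 66.9-fold higher in MyLa. The list was lower in MyLa in camera (median -1.61, adjusted p = 0.00713; adjusted p = 0.581 with an estimated correlation). CD3E was below 5 in MyLa, at least 53.7-fold higher in HH, while CD3D did not pass the test (-0.40, adjusted p = 0.129). Regulatory T cell genes went the other way: 7 of 11 were higher in MyLa and none in HH (7 adjusted over the list alone), with IL2RA at least 230-fold, CTLA4 by at least 5.64 on the log2 scale and the costimulatory receptor TNFRSF9 at least 13.7-fold higher (median 4.75, camera adjusted p = 0.00111; adjusted p = 0.581 with an estimated correlation). Of 19 genes tied to cutaneous T cell lymphoma, 5 were higher in MyLa, DPP4 by at least 79.9-fold, and 7 in HH, CADM1, the ubiquitin ligase NEDD4L (at least 177-fold) and SGCE (at least 177-fold) among them (12 adjusted over the list alone). The inhibitory receptor genes LAG3 (at least 65.5-fold) and CD160 (at least 151-fold) were higher in HH, and the PD-1 ligand CD274 (at least 66.5-fold) in MyLa.

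Cytokine genes were mostly higher in MyLa, 12 of 17 against 1 (13 adjusted over the list alone), with IL1A at least 117-fold, IL15 at least 98.0-fold, LIF at least 56.8-fold and IL13 at least 42.2-fold (median 4.77, camera adjusted p = 0.00464; adjusted p = 0.581 with an estimated correlation). JAK-STAT feedback genes, 13 of 18 higher in MyLa and 3 in HH (16 adjusted over the list alone), had the same camera result (adjusted p = 0.00464; adjusted p = 0.581 with an estimated correlation), with SOCS3 at least 81.2-fold and oncostatin M, OSM, at least 60.6-fold higher in MyLa. Without either HH array 11 of that list were higher in MyLa and none in HH. Of the Th2 list, 5 of 7 genes were higher in MyLa, IL13, IL5 (at least 10.7-fold), MAF (at least 34.6-fold), GATA3 (3.09-fold, adjusted p = 0.00254) and IL4R (2.82-fold), and STAT6 and BATF did not pass (5 adjusted over the list alone; camera adjusted p = 0.0793). Of the Th9 list, 6 of 9 were higher in MyLa, SMAD3 (54.4-fold), STAT5A (17.2-fold), IL9R (4.10-fold), STAT5B (3.61-fold), ETV5 (2.76-fold) and IRF1 (2.21-fold), and IRF4 was higher in HH (3.56-fold), with 7 adjusted over the list alone; BATF and TGFB1 did not pass. The calls of IL4R were lost on leaving out any 1 of the 4 arrays (1.10 to 1.88), and those of IL9R without either HH array (2.09 and 1.98); ETV5 did not pass as the mean of its probe sets (0.67). Without probe sets that can match several transcripts IL1A was lower in MyLa (-1.16). Of the cytokine list, LTA, LTB and CSF1 lost their calls without either HH array. IL32 did not differ by the test (-0.14 ± 0.15, SE; adjusted p = 0.476), ITGAV was higher in HH (2.16-fold) and PTK2 in MyLa. The call of ITGAV was lost without the MyLa IL-32γ array (-0.96) and without either HH array (-1.07 and -1.15). MHC class II and interferon gamma genes were split, 5 of 17 higher in MyLa, GBP5 by at least 43.3-fold, and 6 in HH, among them HLA-DRA, HLA-DQA1 and HLA-DQB1 (at least 186-fold), with 11 adjusted over the list alone.

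Many cell cycle genes were higher in HH. Of 27 G2/M genes, 20 were higher in HH and none in MyLa (20 adjusted over the list alone), led by PLK1 (9.71-fold), KIF20A (9.47-fold), CENPE (7.78-fold) and DLGAP5 (7.47-fold), with a median of -1.82 (MyLa minus HH; camera adjusted p = 5.86e-07; adjusted p = 0.581 with an estimated correlation). Of 26 G1/S and replication genes, 8 were higher in HH, CCNE2 by at least 51.4-fold (it was below 5 on 1 MyLa array) and E2F1 by 4.91-fold (8 adjusted over the list alone; camera adjusted p = 0.000532; adjusted p = 0.581 with an estimated correlation). Histone genes had 6 of 10 higher in HH, H2BC9 by 4.22-fold (6 adjusted over the list alone; camera adjusted p = 0.0284; adjusted p = 0.581 with an estimated correlation), and cholesterol synthesis genes 9 of 17, DHCR7 by at least 26.8-fold and LSS by 8.34-fold (9 adjusted over the list alone; camera adjusted p = 0.000958; adjusted p = 0.581 with an estimated correlation). The p53 targets were higher in MyLa, 10 of 17 and none in HH (10 adjusted over the list alone), with CDKN1A, the cell cycle inhibitor p21, 52.3-fold, AEN 46.4-fold and TP53I3 15.9-fold higher (median 1.80, camera adjusted p = 0.00023; adjusted p = 0.581 with an estimated correlation). Of the metallothionein list 6 of 8 were higher in HH (6 adjusted over the list alone), with MT1E 15.3-fold, MT1G 9.25-fold and MT1X 8.96-fold (camera adjusted p = 0.139). Without the HH IL-32γ array the calls of H2BC9 (-1.93) and TP53I3 (3.88) were lost, and those of MT1G, MT1X, MT1H and MT2A without either HH array, which leaves MT1E and MT1F of the 6. The G2/M genes higher in HH were 11 without the HH IL-32γ array and 9 without the HH control array, and the histone genes 2 and 3, or 4 without the MyLa IL-32γ array. The G1/S and replication genes higher in HH were 5 without the HH IL-32γ array, 6 without the HH control array, 9 without the MyLa IL-32γ array and 12 without the MyLa control array. None of 19 ribosomal protein genes and none of 20 oxidative phosphorylation genes passed.

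Markers of other cell types were few. Of the fibroblast list 5 genes were tested, with COL3A1 at least 287-fold and COL1A1 higher in MyLa and COL6A3 at least 219-fold higher in HH. Of B cell genes, EBF1 was at least 246-fold higher in MyLa, TNFRSF17 at least 342-fold and BLK at least 41.0-fold higher in HH, a call lost for BLK without either HH array. The NK receptor gene KIR3DL1 was at least 35.5-fold and the myeloid integrin gene ITGAM at least 14.6-fold higher in MyLa. No endothelial or melanocyte marker entered the test. Leaving out the HH IL-32γ array left 1409 genes higher in MyLa and 1260 in HH, and leaving out the HH control array left 1580 and 1245.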

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

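The tests weighed in this part were written down before their results were seen. Differences between the lines in their response to IL-32γ were not tested, since each rests on 1 array per condition.

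In 19 genes the values moved by 1.5-fold or more in opposite directions in the 2 lines, fewer than the 33.0 that independent lists would give. Of these, 17 were higher in MyLa and lower in HH. Their MyLa minus HH responses were, in log2, 2.45 for CC2D1A, 2.35 for FSD1, 2.25 for UBALD1, 2.05 for QRICH2, 1.88 for DUS3L, 1.59 for the chloride transporter CLCN7, 1.496 for DUS2, 1.47 for GMDS, 1.44 for ZNF438, 1.43 for LINC00663, 1.42 for SLC5A2, 1.36 for FBXW5, 1.33 for B4GALT2, 1.32 for CHPF2, 1.31 for HEXD, 1.27 for LRFN4 and 1.26 for CLSTN3. The other 2 were lower in MyLa and higher in HH, B3GNT5 (-1.85) and the pluripotency factor gene NANOG (-1.35). As means of their probe sets, HEXD in MyLa (-0.062) and ZNF438 in HH (0.12) had the other sign.

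Control probe sets, which enter no gene comparison, were higher on the IL-32γ array than on the control array at the 5' end of transcripts. The 5' ACTB probe set was higher by 1.69 in MyLa and 0.89 in HH, the 5' GAPDH probe set by 0.68 and 0.15, and the 5' ISGF3A probe set by 0.72 and 0.50. The 18S rRNA probe set was higher by 0.63 and 1.59. The 3' probe sets of ACTB differed by -0.08 and -0.03.

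The number of genes past 1.5-fold was 2.80 times as high in MyLa as in HH. After a loess fit within pairs it was 2.90 times as high, and among 7615 genes at 8 or more on all arrays 7.03 times (717 against 102), which argues against an intensity-dependent bias and against noise of dim genes as the whole cause. Neither test addresses noise of single probe sets at every level. Its SD, estimated from the spread between 2 probe sets of a gene, was 0.376 in MyLa and 0.247 in HH. Both this noise and loss of 5' RNA on the MyLa control array stay open. The dimmer of 2 probe sets gained more than the brightest in 54.8% of genes in MyLa, between the 50% and 55% set in advance, and in 58.0% in HH, where fewer genes moved. The dimmer probe set was only assumed to be the more 5' one, since positions along transcripts were not used here, so these shares do not measure 5' loss directly. A larger response of MyLa to IL-32γ cannot be told apart from this loss or from that noise with 1 array per condition.

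Genes moved the same way in both lines more often than independent lists would. A shared difference in RNA integrity between the control and IL-32γ arrays is a candidate explanation. A change of a gene's total level would leave the gap between its 2 probe sets in place only if both followed it alike. That was not shown, since their responses correlated across genes at r = 0.30 in MyLa and 0.27 in HH. The change in the gap correlated between the lines at r = 0.456 (bootstrap 95% interval 0.424 to 0.486, 4603 genes), above the r = 0.348 of the genes' own responses. Genes are not independent, so the interval is too narrow. A shared response to IL-32γ, including changes in transcript form, stays open as untested.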

How the results depend on the processing

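Counting only genes whose every measured probe set passed 1.5-fold, and the unadjusted p for the lines, were chosen after seeing the data. Where no cause is given below, the cause was not tested. With a 2-fold threshold 280 genes were higher and 163 lower in MyLa, 22 and 72 in HH, 5 moved the same way in both lines and 0 opposite ways, and with the lower threshold planned, a log2 difference of 0.32, 1637, 2261, 358, 1674, 797 and 216, since the threshold sets the number. Without a floor and without the filter on measured genes, 241 were higher and 720 lower in HH, 211 moved the same way and 45 opposite ways, since dim genes then enter. With the floor at 6, 11 moved opposite ways. With the mean of a gene's probe sets 287 were lower in HH and 9 moved opposite ways. With every measured probe set past 1.5-fold, 91 were higher and 67 lower of 5034 genes in MyLa, where the probe set brightest over the 4 arrays alone gave 277 and 250, and 5 and 24 of 5013 in HH, where it gave 35 and 91. Of these, 5 were lower in both lines, 0 higher in both and 0 opposite. Normalising again left the MyLa counts between 802 and 869 higher and 726 and 825 lower.

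No gene passed limma for IL-32γ across lines under any alternative with an adjusted p, and 1045 had an unadjusted p under 0.05. Without the replicate block on the line 0 genes passed and 0 lists were called, against 1 list with it. An estimated correlation, with which camera has only 1 or 2 degrees of freedom, left 0 lists across lines and 0 of 9 between lines. Leaving out each array used the fit without the block, since the block leaves no residual degree of freedom, and gave 0 genes each time. Between lines, leaving out each array in turn gave 1409 to 1913 genes higher in MyLa and 1245 to 1843 higher in HH, the lone array being assumed to vary like the rest. Without a fold minimum 2981 were higher in HH and 3222 in MyLa. Treatment as a replicate block gave 2187 and 1965 and the same number of lists, 9. The control arrays alone gave 2138 and 2074 at 2-fold with no test.

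As the mean of probe sets HEXD (-0.062), ICAM1 (0.072), JAK2 (0.12), JAK3 (-0.21) and TIAM1 (0.25) changed sign in MyLa, and ZNF438 (0.12) in HH. Without probe sets that can match several transcripts MEF2C in MyLa (0.66), PTP4A3 in HH (-0.042) and IL1A between lines (-1.16) did, because another probe set then stands for the gene. Of 211 IL-32γ differences of named genes, 112 moved by more than the spread between probe sets or changed sign under at least 1 alternative. Of 185 differences between lines, 59 lost their call or changed sign under at least 1, mostly on leaving out an array or without a floor. Of 50 list medians 2 moved, both toward 0 without a floor, the regulatory T cell list in HH and the fibroblast list in MyLa. Signal below 5 limits the rest: a gene under it has a bound and no fold.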

Other observations

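The test in this part was written down before its result was seen, and the allowance for the spread between probe sets was added after it. The gene groups below were picked from the fixed lists after their values were seen.

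Of 21 integrated stress response genes compared between the lines, 10 were higher in MyLa and 2 in HH by limma (12 adjusted over the list alone). The list as a whole was not called (camera adjusted p = 0.0969), nor was that of type I interferon genes (0.452). CHAC1, which degrades glutathione, was 21.4-fold, the transcription factor ATF5 11.9-fold and TRIB3 8.66-fold higher in MyLa, while the serine synthesis enzyme PHGDH was at least 184-fold and VLDLR at least 34.7-fold higher in HH. Of 20 type I interferon genes, 9 were higher in MyLa and 3 in HH (12 adjusted over the list alone), with RSAD2 at least 114-fold, MX2 32.6-fold and IFIT5 at least 22.1-fold higher in MyLa, and HERC5 at least 57.9-fold and EPSTI1 at least 18.5-fold higher in HH.

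Feedback genes of MAP kinase signalling were divided, 10 of 21 higher in MyLa and 9 in HH (19 adjusted over the list alone; camera adjusted p = 0.582). DUSP5 was at least 40.1-fold and EGR1 14.6-fold higher in MyLa, and DUSP4 7.06-fold and PHLDA1 6.59-fold higher in HH. Without the HH control array 6 of the 9 were still higher in HH. NF-κB targets were higher in MyLa in 13 of 23 and in HH in 3 (16 adjusted over the list alone; camera adjusted p = 0.121), with CXCL8 at least 17.1-fold and CD83 9.92-fold higher in MyLa and NFKB1 5.46-fold higher in HH. The integrin ITGB7 was higher in HH, with a value of 5.18 on the MyLa control array and 4.91 on the MyLa IL-32γ array against 11.10 and 10.57 in HH.

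Metallothionein genes were higher with IL-32γ in MyLa, and a zinc-like response is a candidate explanation. SLC30A1, a zinc exporter that is no metallothionein, differed by 0.033 in MyLa, under the log2 difference of 0.32 set in advance as the bound against it. That gap is smaller than the noise of a single probe set (SD 0.38), estimated from the spread between 2 probe sets of a gene, so the value does not settle it. Paralogs sharing probes, and the 5' control difference of the same 2 arrays, also stay open.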
